A study of Bombyx mori with 8 samples.

How the data were processed

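The series measured G-quadruplexes (G4, DNA structures folded from runs of guanines) in silkworm (*Bombyx mori*) chromatin by CUT&Tag, in which an antibody tethers a Tn5 transposase that cuts nearby DNA and adds sequencing adaptors in place. The labels describe 8 samples. Peak lists of 4 of them were analysed, 2 libraries of brain and 2 of fat body, all labelled with strain P50, the stage code L5D3 and BG4, an antibody fragment that binds G4 structures. The remaining 4 samples (an IgG library, a brain library at the stage coded P0 and 2 libraries of the ovarian cell line BmN) were not analysed here. Nothing in the labels says whether 2 replicates of a tissue came from separate animals, so the spread between them may be technical.

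Each library has its own peak list, in narrowPeak layout, and no list pools replicates. Per the submitters' processing notes, Trim Galore, Bowtie2, Picard, deepTools 3.3.0 and MACS2 2.1.0 were used; the notes as used here give the tools no order or settings. The genome build is not given in the sources used here. In the deposited lists, the score is 10 times the −log10 q rounded down (in over 99.9% of peaks of each list), the fold enrichment (a ratio) is the summit's height over the peak caller's local background, and 2 further columns hold −log10 p and −log10 q; all of these are the authors' values. The lowest −log10 q was between 5.01 and 5.21 in the 4 lists, so each list stops at a q of 1e-05. Fold enrichment was used to describe, rank or filter the peaks of each list and in the rule for named regions; folds are given per list and were not tested between lists.

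The text inside the deposited peak names differs from the labels. All peak names of both fat body lists carry 1H6, the name of another antibody against G4 structures, where the labels say BG4. The names of brain replicate 1 carry BG4, and those of brain replicate 2 carry G4 and name no antibody. The names of the other 3 lists carry the stage text 5L4D (in varying case and spelling) where the labels say L5D3, and those of fat body replicate 2 carry the letter W in its place. The fat body names share the start of a library code, the names of brain replicate 2 have another code and those of brain replicate 1 have none, and brain replicate 2 alone records a mapping quality limit of 20 and duplicate removal. Groups were kept as labelled. If the names are right, the fat body lists differ from brain replicate 1 in antibody as well as tissue, the antibody of brain replicate 2 is open, and the lists cannot tell antibody and tissue apart.

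Coordinates are 1-based, in the sequences of the assembly the lists use, which has 28 long numbered sequences, many short unplaced sequences and a mitochondrial genome; sequences are called here by their number in that assembly. The gene table given for the organism belongs to another assembly (ASM3026992v2) and no genome sequence was used here. Promoter share, G4 motif share, promoter genes and the 27 gene lists set out before the data were examined were therefore not run, and regions are given by coordinates with no gene or feature annotation.

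The summit height in fragments (pileup) and the local background of each peak were worked out from the authors' fold and −log10 p, taking fold as (pileup + 1)/(background + 1) and p as the Poisson upper tail. The pileup came out whole, within 0.02, for 100% of peaks in each list. Backgrounds above the list's lowest value (its floor) fell on whole steps, within 0.1 step, for 98.5% to 100% of the peaks tested. A step was the fragment length divided by 2 times 10 kb, as when the 2 ends of each fragment are counted over 10 kb. Fragment lengths were 295.0, 212.8, 279.9 and 293.1 bp in brain replicates 1 and 2 and fat body replicates 1 and 2. The step size is that of a background made from the library's own fragments. On simulated peaks, 100% of 4992 pileups came back exactly. The number of reads behind each list is unknown; the median summit pileup was 49, 66, 58 and 43 fragments in the same order, and that depth limits how weak a peak could be called.

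Peaks of different lists were counted as shared when they overlapped by at least 1 bp. The share of each list overlapped by another was compared with 1000 circular shifts of the list within its sequences (one-sided permutation p, smallest possible 0.001, Benjamini-Hochberg over the 12 ordered pairs; 200 shifts, smallest 0.005, within 10 equal bins of a list by fold). Jaccard indices are shared over combined covered bases. With 2 against 2 libraries the smallest exact p between tissues is 0.333, so no p is given for tissue. The 4 lists were merged into regions, and a region was called brain-restricted or fat-body-restricted when both lists of that tissue and neither of the other called it; counts were set beside the 2 other ways to pair the libraries and beside 100 shifts. On simulated lists, all 350 planted restricted regions were found. Restricted regions were compared between sequences and between 500-kb windows holding at least 5 of them with two-sided Fisher exact tests, Benjamini-Hochberg adjusted; regions are not replicates, so these p-values describe the lists. Peak counts were also taken in 100-kb windows. Confidence intervals of shares are exact binomial (Clopper-Pearson, 95%) and cover counting error only.

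The rule for named regions, set before the data were examined, took the 5 brain-restricted, 5 fat-body-restricted and 5 shared regions with the highest value of the smallest fold among the lists that call them. Alternatives set before the data were examined were a −log10 q of at least 5, equal list lengths (the 5894 peaks with the highest −log10 q of each list), long sequences only, overlap of 50% of the shorter peak, summits within 250 bp, and each library left out. For the difference of Jaccard indices, the regions in all 4 lists and the odds ratio on sequence 1, all alternatives were chosen after the data were seen. Alternatives added afterwards were a −log10 q of at least 20 and a raised background floor in the brain lists (5.42 and 7.18 fragments in replicates 1 and 2), with p recomputed from the pileup. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.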

Results

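G4 CUT&Tag peaks of silkworm larval brain and fat body, the insect organ of fat storage and intermediary metabolism, were compared as 4 lists, 2 replicates per tissue. Brain replicate 1 held 6759 peaks and brain replicate 2 held 33925, a mean of 20342 ± 19209 (SD, n = 2). Fat body replicates 1 and 2 held 8556 and 5894 peaks, a mean of 7225 ± 1882 (SD, n = 2). The brain lists differed 5.02-fold in length and the fat body lists 1.45-fold, so the difference in mean peak number between tissues was smaller than the spread between the brain replicates. Peaks covered 3797 and 17765 kb in the brain lists and 5175 and 3406 kb in the fat body lists. Median peak widths were 495 and 405 bp in brain and 520 and 515.5 bp in fat body. The authors' fold enrichment at the summit had medians of 5.14, 5.17, 5.03 and 6.81 in brain replicates 1 and 2 and fat body replicates 1 and 2. Peaks with a fold above 12 made up 0.533%, 9.80%, 1.30% and 7.16% of the lists in the same order. The peak names of both fat body lists carry the name of a different G4 antibody, 1H6, from the BG4 of their labels, those of brain replicate 2 carry G4 with no antibody named, and those of fat body replicate 2 have a different stage text from the other lists, which applies to each comparison between the tissues here.

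How far replicates of one tissue mark the same places sets the error for any comparison of tissues. In fat body, 4154 of 5894 replicate 2 peaks (70.5%) overlapped a replicate 1 peak, and 48.7% of replicate 1 peaks overlapped replicate 2, where shifted lists gave 2.34% and 1.61%. In brain, 4071 of 6759 replicate 1 peaks (60.2%) overlapped a replicate 2 peak, where shifted lists gave 8.08%. In the other direction 12.5% of the longer replicate 2 list overlapped replicate 1, where shifted lists gave 1.62%. All 4 shares were above each of 1000 shifts (adjusted permutation p = 0.001, the smallest they can give). At equal list lengths, 60.3% of fat body peaks were shared between replicates, and the share of brain replicate 1 peaks in replicate 2 was 12.1%, still above the 1.77% of shifted lists. Equal lengths kept the 5894 peaks of each list with the highest −log10 q. In brain replicate 2 this changed which peaks were compared as well as how many.

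The strongest peaks of 3 lists were those most often found elsewhere. Each list was split by fold into 10 bins of equal size, bin 10 being the highest. From bin 1 to bin 10, the share of fat body replicate 2 peaks overlapped by fat body replicate 1 went from 45.9% to 95.8%, and by brain replicate 1 from 21.4% to 85.8%. For brain replicate 1 peaks, the share overlapped by brain replicate 2 went from 40.4% to 80.3%. Brain replicate 2 differed. The share of its peaks overlapped by brain replicate 1 was 4.75% in bin 1, reached 21.9% in bin 7 and was 3.33% in bin 10, where shifted lists gave 1.97% (permutation p = 0.005, the smallest 200 shifts can give). In bin 10, which held 3393 peaks with a median fold of 15.6 and a median width of 831 bp, fat body replicate 1 overlapped 2.51% and fat body replicate 2 overlapped 1.97%, where shifted lists gave 2.50% and 1.71% (permutation p = 0.517 and 0.129 from 200 shifts).

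**Figure D1:**
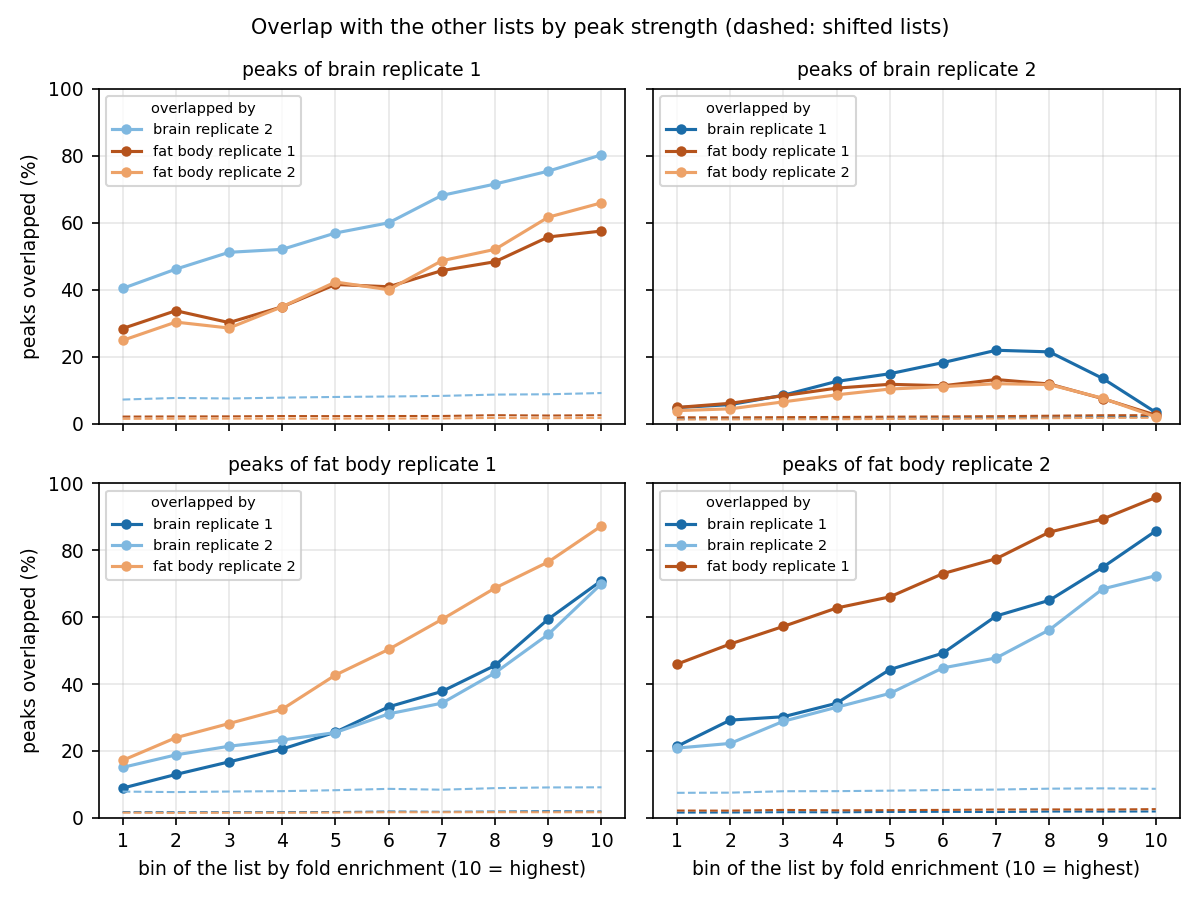
Percentage of peaks overlapped by each other list (y axis) in 10 equal bins of a list by the authors' fold enrichment (x axis, bin 10 the highest), one panel per library; dashed lines give the mean of 200 shifted lists. The share reaches 95.8% in bin 10 of fat body replicate 2 and is 3.33% or less in bin 10 of brain replicate 2.

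The tissues were compared by the share of covered bases that 2 lists have in common. The fat body replicates had the highest Jaccard index of the 6 pairs, 0.349. Brain replicate 1 came next with fat body replicate 2, at 0.265, and with fat body replicate 1, at 0.186. Brain replicates 1 and 2 had an index of 0.0726, and brain replicate 2 had 0.0464 and 0.0445 with the fat body lists. An index cannot exceed the shorter covered length over the longer. Brain replicate 2 covered 17765 kb, against 3797 kb in brain replicate 1 and 5175 and 3406 kb in fat body. Its indices are thus capped low by its length, and the full-list indices and their means are not on 1 scale. The bases that brain replicate 1 had in common with the other lists came to similar lengths, 1459 kb with brain replicate 2 and 1409 and 1508 kb with fat body replicates 1 and 2. At equal list lengths its index was 0.0391 with brain replicate 2, 0.195 with fat body replicate 1 and 0.273 with fat body replicate 2. By number of peaks, 41.7% and 42.9% of brain replicate 1 peaks overlapped fat body replicates 1 and 2 and 60.2% overlapped the much longer brain replicate 2. Shifted lists gave 2.28%, 1.54% and 8.08% in the same order (adjusted permutation p = 0.001 for each). The shares were thus 18.3, 28.0 and 7.45 times those of shifted lists. With a shifted share of 8.08%, even full overlap with brain replicate 2 would have given a ratio below those of the fat body lists. The order of these ratios therefore does not rank the lists. Pairs of one tissue averaged 0.211 (n = 2) and pairs of different tissues 0.136 ± 0.109 (SD, n = 4), so the difference of 0.0754 was smaller than the spread between the pairs of different tissues. These 4 pairs reuse the same 4 libraries and are not independent. Their spread is mostly the gap between pairs with brain replicate 1 (0.186 and 0.265) and pairs with brain replicate 2 (0.0464 and 0.0445). The difference between same-tissue and different-tissue pairs was 0.304 without brain replicate 1 and 0.124 without brain replicate 2. It turned to -0.0821 without fat body replicate 1 and to -0.0438 without fat body replicate 2.

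Merging the 4 lists gave 41892 regions, of which 33884 (80.9%) were called in 1 list, 28253 of them in brain replicate 2. All 4 lists called 1541 regions, where shifted lists gave a mean of 0.64 and at most 4. Shifts do not account for places that give peaks whatever the antibody, and the IgG library was not analysed. A region in all 4 lists is therefore not shown to hold a G4. These shared regions had a median width of 862 bp, and median folds of 6.19, 6.0, 7.17 and 9.04 in brain replicates 1 and 2 and fat body replicates 1 and 2. They made up 37.7% of the 4088 regions that both brain lists called and 37.2% of the 4142 that both fat body lists called. The number of shared regions was 256 at equal list lengths, 821 with a −log10 q of at least 20, and 2365 in the remaining 3 lists without brain replicate 2. The shared region that ranked first lies on the short sequence 216, at 15442 to 16152, with folds of 30.8 and 29.7 in brain and 31.3 and 26.4 in fat body. Next came sequence 25 at 6625101 to 6625791, with folds of 19.4 and 14.6 in brain and 23.2 and 25.7 in fat body. The other shared regions named by the rule were sequence 25 at 5612121 to 5612511, sequence 1 at 10136620 to 10137611 and sequence 14 at 5642005 to 5642606, whose smallest folds were 12, 12 and 11.3. With the raised brain background floor the smallest fold on sequence 216 was 10.1 and that of the region ranked next 9.65, and that next region was not called in all 4 lists at equal list lengths.

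**Figure D2:**
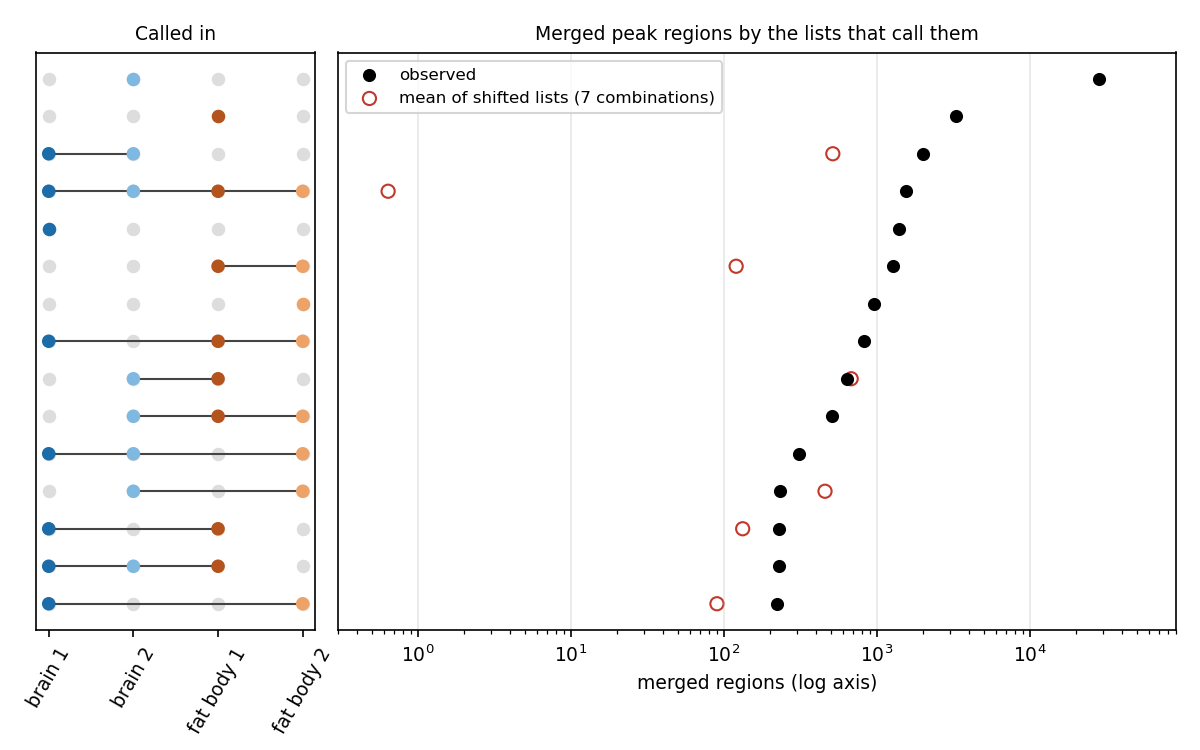
Number of merged regions (x axis, log scale) for each of the 15 combinations of lists that call them, shown by coloured dots on the left; open circles give the mean of 100 sets of shifted lists for 7 combinations. Regions in brain replicate 2 alone number 28253, and the 1541 regions in all 4 lists lie farthest above their shifted mean of 0.64.

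Regions called in both brain lists and in neither fat body list numbered 2008, where shifted lists gave a mean of 515 and at most 587. Regions called in both fat body lists and in neither brain list numbered 1266, where shifted lists gave a mean of 120 and at most 153. Pairing the lists by replicate number gave 229 and 232 regions and the crossed pairing 223 and 635, so the pairing by tissue gave the most in both places. Raw counts depend on list length. Shifted lists gave means of 133 and 458 for the pairs by replicate number and 90.1 and 679 for the crossed pairs. The 232 and 635, both with brain replicate 2, were thus below their shifted means, and the 229 and 223 above. Such counts leave out regions that a further list also calls, and all 4 lists called 1541 regions against a shifted mean of 0.64. A count below its shifted mean therefore does not show less overlap than in shifted lists. By peaks, fat body replicates 1 and 2 overlapped 8.77% and 7.78% of brain replicate 2, where shifted lists gave 2.13% and 1.44%. With 3 pairings no p under 0.333 can be reached. Brain-restricted regions were 49.1% of those in both brain lists, and fat-body-restricted regions 30.6% of those in both fat body lists. At equal list lengths the counts were 354 in brain and 1479 in fat body, and brain replicate 1 then shared 648 regions with fat body replicate 2 alone, more than with brain replicate 2. These counts mix list length with the choice of peaks, since only the brain replicate 2 peaks with the highest −log10 q were kept. A −log10 q of at least 20 left 871 and 787. With 1 brain list, the brain-restricted count was 30367 without brain replicate 1 and 3399 without brain replicate 2. The fat-body-restricted count was 2263 without fat body replicate 1, 4576 without fat body replicate 2 and 2100 without brain replicate 1.

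The brain-restricted regions with the highest folds in both brain lists were sequence 216 at 7622 to 8163 (folds 18.8 and 15.6), sequence 121 at 23615 to 23967 (15.7 and 14.4), sequence 11 at 12940051 to 12940626 (12.6 and 12.7) and at 13536933 to 13537397 (12.2 and 15.4), and sequence 25 at 12974066 to 12974544 (11.8 and 12.5). The first lies 7496 bp from the nearest fat body peak, which is part of the region of sequence 216 called in all 4 lists, and neither fat body list has a peak on sequence 121. The last had summit pileups of 89 and 131 fragments and lies 29209 bp from the nearest fat body peak. It was also the only one of these 5 still called in both brain lists at equal list lengths, and the smallest folds of the first 4 were 5.25, 5.13, 8.10 and 4.20 with the raised brain floor.

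The fat-body-restricted regions with the highest folds were sequence 15 at 6070041 to 6070642, with folds of 20.4 and 19.3 and summit pileups of 280 and 117 fragments, and sequence 17 at 9037826 to 9038260, with folds of 15.5 and 17.7. Sequence 4 at 8459000 to 8459582 had folds of 15.2 and 15.6, sequence 11 at 10106549 to 10106998 had 13 and 14.4, and sequence 1 at 18743772 to 18744261 had 11.9 and 13.3. All 5 were still called in both fat body lists at equal list lengths. The nearest brain peak lay 8485 bp from the first, 1808 bp from the second and 27447 bp from the region on sequence 4. A peak of brain replicate 2 lies 543 bp from the region on sequence 11, whose nearest brain replicate 1 peak is 166285 bp away.

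Restricted regions of the tissues were spread differently over the 28 long sequences in 3 cases. Sequence 1 held 111 of 1996 brain-restricted regions (5.56%) and 28 of 1265 fat-body-restricted regions (2.21%), an odds ratio of 2.60 (two-sided Fisher exact test, adjusted p = 5.32e-05 over 28 sequences). Sequence 20 held 2.20% and 4.27% (odds ratio 0.506, Fisher exact adjusted p = 0.0143) and sequence 8 held 2.66% and 4.58% (odds ratio 0.568, adjusted p = 0.0364). Sequence 1 spans 4.64% of the long sequences. Its peak density was lower than the median of the other sequences in all 4 lists, at 0.895 and 0.644 of it in the brain lists and 0.612 and 0.573 in the fat body lists. The odds ratio on sequence 1 was 1.53 without brain replicate 1 (Fisher exact adjusted p = 0.0173), and 2.50 at equal list lengths, where it no longer passed (Fisher exact adjusted p = 0.0687). In 500-kb windows, 0 of 277 passed an adjusted p of 0.05 and 29 had an unadjusted Fisher exact p under 0.05. The lowest p was on sequence 19 from 7500001 to 8000000, with 0 brain-restricted and 8 fat-body-restricted regions (Fisher exact adjusted p = 0.140). The comparison of sequences and windows was chosen after the data were seen.

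**Figure D3:**
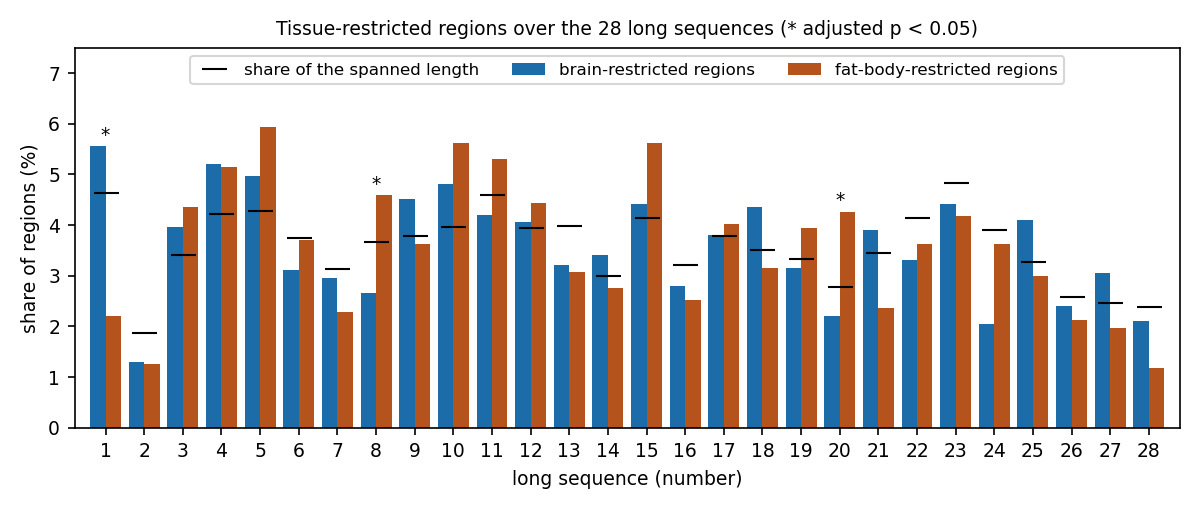
Share of all brain-restricted (blue) and fat-body-restricted (brown) regions on each of the 28 long sequences (y axis, percent), with each sequence's share of the spanned length as a black line and an asterisk for an adjusted p under 0.05. Sequence 1 holds 5.56% of brain-restricted and 2.21% of fat-body-restricted regions.

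In all 4 lists, more 100-kb windows were empty than under random placement, which took every window as equally open to a peak. The variance of window counts over their mean was 2.87 and 1.77 in fat body and 1.38 and 1.26 in brain. Of the 100-kb windows, 39.6% and 40.1% held no peak of fat body replicates 1 and 2, where random placement of as many peaks gives 14.7% and 26.7%. In brain replicate 1, 28.4% of windows were empty against 22.1%, and in brain replicate 2 0.226% against 0.0549%. The longest stretch without a peak in either fat body list was 1253 kb, on sequence 25 from 12944857 to 14198343. It held 11 peaks of brain replicate 1, 116 of brain replicate 2 and 8 brain-restricted regions, among them the named one at 12974066. Over all of sequence 25, brain replicates 1 and 2 had 17.6 and 80.7 peaks per Mb. Such stretches were picked for holding no fat body peak, so any region in them that both brain lists call is brain-restricted by definition. The next longest, on sequences 12, 13 and 26, were 1181, 1181 and 1137 kb long and held 2, 4 and 4 brain-restricted regions. The fifth longest, on sequence 18 from 14096161 to 15207210, held 8, as many as the stretch on sequence 25.

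**Figure D4:**
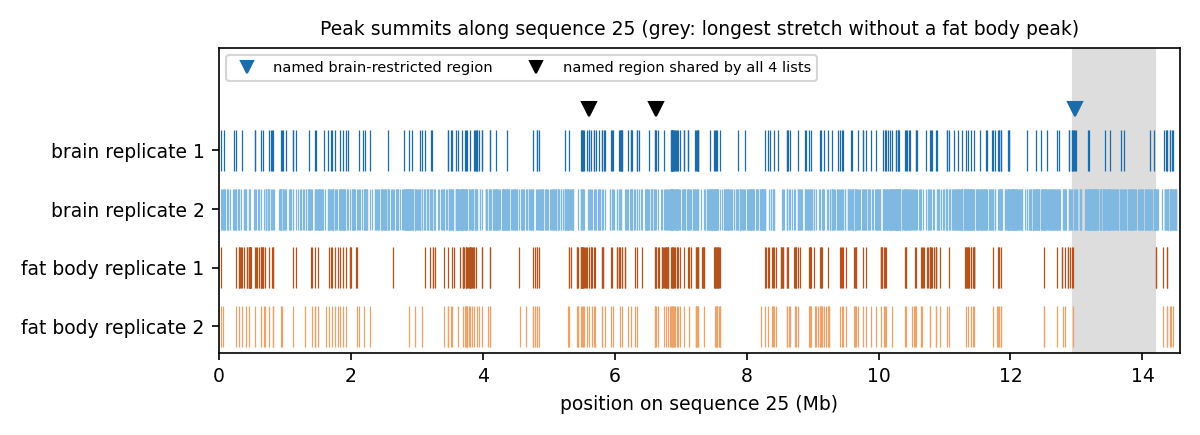
Peak summits of the 4 lists along sequence 25 (x axis, position in Mb; one row of ticks per library). The grey band is the longest stretch with no fat body peak, 1253 kb, and triangles mark the named regions, the blue one being the brain-restricted region at 12974066.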

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

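Brain replicate 1 had 1 peak on the mitochondrial genome, from position 1 to 742, with a summit pileup of 23 fragments and a fold of 11.7 over a background at the list's floor. It stands out because it lies outside the nuclear sequences. The overlaps and merged regions counted it, and the comparisons of long sequences and of windows did not. The other 3 lists hold no mitochondrial peak, which says nothing of their mitochondrial reads since lists hold called peaks only. No explanation was tested.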

How the results depend on the processing

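The overlap between replicates stayed above shifted lists under every alternative run (−log10 q limits of 5 and 20, equal list lengths, long sequences only, 50% overlap, summits within 250 bp, raised brain floor), from 12.1% to 65.7% in brain and from 60.3% to 72.0% in fat body. The planned limit of 5 on −log10 q removed no peak and so tests nothing. Equal list lengths lowered the brain-restricted count to 354 and the regions in all 4 lists to 256. They kept 5894 of 33925 brain replicate 2 peaks, those with the highest −log10 q, and the strongest peaks of that list by fold overlapped the other lists least. The effect of list length therefore cannot be told apart from that of the peaks chosen. A −log10 q of at least 20, chosen after the data were seen, lowered brain-restricted, fat-body-restricted and shared regions to 871, 787 and 821, since it leaves fewer peaks. Long sequences only, 50% overlap, summits within 250 bp and the raised brain floor, where run, moved none of these counts by over 1.5 times. For 50% overlap and summits within 250 bp, peaks of the tissue's replicate 1 were counted in place of merged regions. They gave 1891 and 1859 in brain and 1341 and 1389 in fat body. The same rule decided overlap with the other tissue, so it also made exclusion looser. With 1 library left out at a time, which changes how many lists a region needs, the brain-restricted count ranged from 2233 to 30367, the fat-body-restricted count from 1775 to 4576 and regions in all remaining lists from 1764 to 2365. The difference between same-tissue and different-tissue Jaccard indices ranged from -0.0821 to 0.304; it was 0.304 without brain replicate 1 and 0.124 without brain replicate 2, and it reversed to -0.0821 without fat body replicate 1 and -0.0438 without fat body replicate 2, because the remaining same-tissue pair was then that of brain. The odds ratio on sequence 1 stayed above 1 in each alternative run, from 1.53 to 3.57, but at equal list lengths, with fewer regions, it was 2.50 with a Fisher exact adjusted p of 0.0687; the adjusted p was at most 0.0173 in the others. Of the 15 named regions, 10 were still called in all their lists at equal list lengths, and 12 lie on long sequences. No paired analysis was possible because the peak lists give overlaps and counts with no fit to which a replicate block could be added. Promoter share, G4 motif share, promoter genes and the gene lists, with their alternatives, were not run. Read depth is unknown, so a region missing from a list is one not called at that library's depth, not one shown to lack a G4. A called region, also one shared by lists, was not set against the IgG library and is not shown to hold a G4.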

Other observations

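All tests in this part were chosen after the results they bear on were seen, except those of unplaced sequences and of shared peaks on sequence 1, whose outcomes had not been seen.

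Across 4429 windows of 100 kb, fat body replicates 1 and 2 placed their peaks alike (Spearman correlation of counts 0.76), and brain replicate 1 followed both (0.48 and 0.54). Brain replicate 2 followed none of them, with 0.03 against brain replicate 1 and -0.13 and -0.06 against the fat body lists. Windows are not independent, so no p is given. At equal list lengths, 1785 regions were called in brain replicate 1 and both fat body lists but not in brain replicate 2, and 5100 in brain replicate 2 alone. Unplaced sequences held 1.17% of brain replicate 2 peaks, with a median fold of 12, against 0.577% in brain replicate 1 and 0.164% and 0.102% in the fat body lists.

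The strongest brain replicate 2 peaks overlapped the other lists less than its mid-strength peaks: 3.33% of the 10% of its peaks with the highest fold (bin 10; 95% interval 2.75% to 3.99%) overlapped brain replicate 1, above the 1.97% of shifted lists, against 18.2% in bin 6. These shares are the pattern itself, so they do not decide whether the length or depth of the list plays a part. Of bin 10, 24.7% had a local background under the raised floor, against 15.7% of the other peaks, but that floor is an assumed level, so a floor set too low stays open. Unplaced sequences held 5.92% of bin 10 against 0.642% of the other peaks. They are over-represented in bin 10, but most of it lies elsewhere, which argues against them as the main cause. A different target, preparation, read filtering or sample behind that library stays open and was not tested, as does a difference between brain samples. Its peak names alone record a mapping quality limit of 20 and duplicate removal.

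In the brain lists the median local background was 8.68 and 6.83 times the floor, against 1.71 and 1.63 times in fat body. Reads gathered in a small part of the genome could raise it, but in brain replicate 2 the fragments counted in disjoint 10-kb windows around summits, covering 45.2% of the span, were already 3.16 times what the floor allows for the whole span (1.16 times in brain replicate 1). A genome size setting larger than the span could give a ratio over 1, so that setting is a candidate explanation for the brain lists. The ratio of 3.16 is no separate test of it, since any ratio over 1 would have done the same. The fat body ratios, 0.255 and 0.198, come from windows covering 11.5% and 9.47% of the span and leave open which setting those lists had. Under a low floor, weak peaks would pass more easily in low-background places; raising the floor left 1871 brain-restricted and 1274 fat-body-restricted regions.

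Fewer reads from sequence 1 in the fat body libraries could give the excess of brain-restricted regions there, and its local background was 0.815 and 0.735 of the other sequences' median in fat body, but also 0.898 and 0.727 in brain. Among brain replicate 1 peaks with a fold of at least 5.90, 47.2% of 108 on sequence 1 were also called in a fat body list against 64.0% of 2132 on the others, a difference of -16.8 percentage points (two-sided Fisher exact p = 0.000672). The difference was -15.8 points in the rest of the list and -15.0 over all peaks. The test had taken strong peaks to be found even with fewer reads, but on the other sequences only 64.0% were, so fewer reads stay open. The sex of the animals was not analysed here, and a tissue difference and an antibody difference both stay open.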
